A study of Homo sapiens with 9 samples.

How the data were processed

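RNA sequencing was done on 9 libraries of MDA-MB-231-D3H2LN cells: wild type, JAG1 knockout clone 1 and JAG1 knockout clone 2, with 3 replicates each. Per the labels' protocols, cells grew in high-glucose DMEM with 10% fetal bovine serum, RNA was extracted with a column kit, and a sequencing service made the libraries at a stated depth of 20000000 read pairs of 150 bases. The authors deposited raw counts per gene in 2 tables, each holding the wild-type libraries and those of 1 clone. The wild-type columns were identical in both tables (3 of 3) and were used once. Per the submitters' processing notes, STAR, featureCounts, Subread and DESeq2 were named with the build GRCh38, but without versions or roles. The file headers carry gene coordinates and lengths, while the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

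Each table lists 56505 gene symbols, of which 31961 had a count in any library. Total counts per library ran from 16890890 to 22456164. Symbols were matched to GENCODE release 29 (37335 symbols, 66.07%) for gene type and GC content, and 98.64% of those overlapped in position. Another 625 symbols took their type from a RefSeq synonym, and 137 symbols listed on several chromosomes were left out of the chromosome scan. Of counts up to 50, 45.15 to 47.91% were even, so counts did not come in pairs. Replicates differed by far more than sampling noise, with a chi-square per gene of 17.7 to 62.6 between libraries of a group, so none was treated as a duplicate.

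Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: TMM normalisation, filterByExpr by group with a minimum count of 10 (16921 genes kept), and a robust quasi-likelihood fit of all 9 libraries as 3 groups with 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05, and the biological coefficient of variation was 20.3%. All comparisons of single genes are two-sided. CPM values use TMM-scaled library sizes. For a group at 0 counts, a fold is given as a bound from a floor of 3 counts over the group, and for 1 to 3 counts as a ratio with a 95% counting interval. Reads without molecular identifiers are not independent molecules, so these bounds and intervals cover counting error only. Genes called in both clones were compared with the product of list sizes over the genes tested, and with 20 simulated pairs of unchanged groups against the real wild-type libraries. Their shared mean carried the error of the wild-type mean, from negative binomial draws or from the residuals of the real libraries, a construction set after the data were seen.

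The comparisons, the 25 gene lists, the naming rule and most alternatives were fixed before the data were examined. Lists (639 entries, 638 matched to a symbol, 19 of them by an older symbol) came from general knowledge, and none was chosen on these samples. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry tests whether its members move, on balance, one way. Of the lists camera called with the preset correlation, 0 of 13 in clone 1, 0 of 8 in clone 2 and 0 of 3 between the clones held with the estimated one (smallest adjusted p 0.235, 0.329 and 0.667), and 4, 3 and 3 of them passed fry. The naming rule took JAG1; the 8 largest increases and 8 largest decreases per clone among protein-coding genes that were called, reached a mean of 5 CPM in the higher group and had no overlap between libraries; up to 12 per direction by the smaller change among genes called in both clones (10 higher genes qualified); the 5 largest differences per direction between the clones; up to 4 members per list with the smallest adjusted p in either clone; and any detected member of the Notch lists. Uncharacterised symbols were passed over.

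Replicate numbers are shared between groups, but nothing in the labels says what a number marks. Deviations from the group means correlated between wild-type and clone 2 libraries of the same number at 0.223, 0.269 and 0.246, each above that with any other number. With 3 libraries per group such a match can arise without pairing. In the other pairs of groups only number 1 was the best match. Whether the numbers pair the samples is therefore not known. A fit with the replicate number as a block was run for each comparison. The other alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, a test against 1.5-fold (glmTreat), a fit of only the 6 libraries compared, and leaving out each library. Added after the data were seen were a correction for GC content and length, which took a smooth trend out of each library for the 87.3% of tested genes with a known GC content, the same with the block, and the log2 share of mitochondrial mRNA as a covariate.

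On simulated counts for the 16921 genes with 200 changed, edgeR recovered 95.5% of 4-fold changes and 67.2% of 2-fold changes in each clone, and 30.3% of 1.5-fold changes in clone 1 and 10.4% in clone 2. Of the genes called there, 6.9% in clone 1 and 4.6% in clone 2 had been given no change. Counts were drawn independently for each gene, with the same mean and dispersion in both clones before the planted changes. Along chromosomes, medians of 50 neighbouring tested genes were compared with 10000 random gene sets, using coordinates from the file headers. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Amplicon sequencing and western blots that the labels mention were not used here.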

Results

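RNA sequencing compared 3 states of MDA-MB-231-D3H2LN, a derivative of the human breast cancer line MDA-MB-231: wild-type cells and JAG1 knockout clones 1 and 2, with 3 libraries each. JAG1 encodes a cell-surface ligand of the Notch receptors. Per the labels, Cas9 complexes cut separate places of one JAG1 exon, and each homozygous clone was grown from a single cell. The series title places the work in a study of tumour-cell JAG1 and lymph node metastasis, and the comparisons ask which transcripts differed in the knockout clones. Total counts per library ran from 16890890 to 22456164, and 16921 genes had enough counts to be tested. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each clone is 1 line, and the results describe these lines.

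JAG1 itself lay on chromosome 20 (GRCh38, 10637684 to 10674107, minus strand) and had lower counts in all 6 knockout libraries than in any wild-type library. Its raw counts were 5069, 3803 and 3592 in wild-type replicates 1, 2 and 3. They were 2130, 1699 and 1657 in clone 1, and 1230, 1406 and 1190 in clone 2. Normalised expression was 195.9 ± 44.7 CPM (counts scaled to library size) in wild type, 94.5 ± 14.9 in clone 1 and 66.9 ± 9.87 in clone 2 (mean ± SD, n = 3 each). By edgeR's quasi-likelihood test, JAG1 fell by 1.05 on the log2 scale in clone 1 (SE 0.18, adjusted p = 0.00312) and by 1.55 in clone 2 (SE 0.18, adjusted p = 0.000130). The median log2 fold change of all 445 tested genes of chromosome 20, relative to all genes, was −0.284 in clone 1 and 0.073 in clone 2. JAG1 was also lower in clone 2 than in clone 1 (log2 difference −0.50, SE 0.18, adjusted p = 0.0398), a call lost without clone 1 replicate 1 or 3 or clone 2 replicate 3 (adjusted p of up to 0.172). The counts cover every exon of the gene, so an edit in 1 exon need not lower them, and they do not measure the protein.

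**Figure D1:**
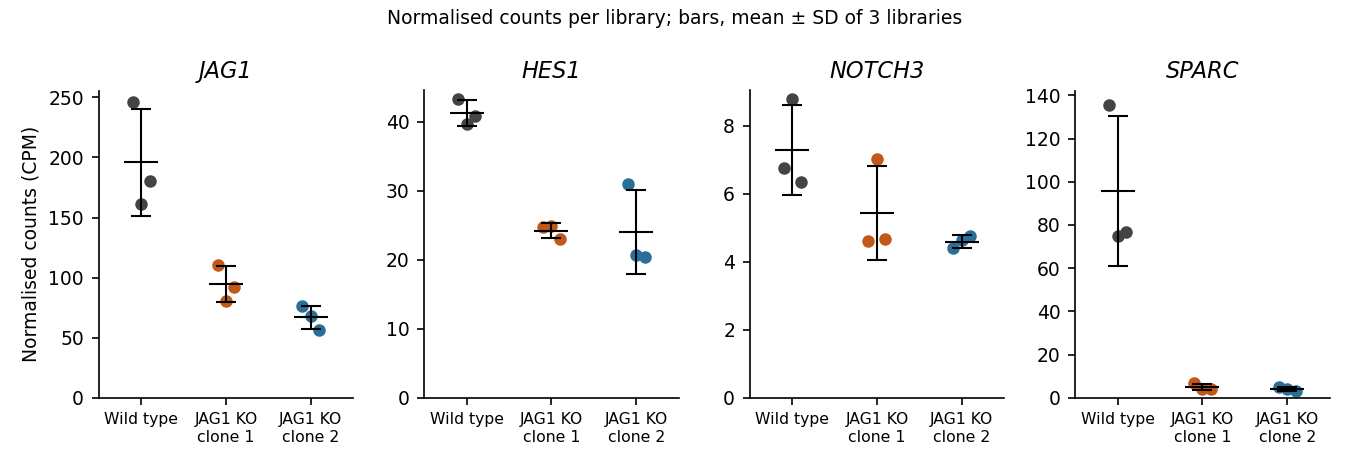
Normalised expression (CPM, vertical axis from 0) of JAG1, HES1, NOTCH3 and SPARC in the 9 libraries, with points for single libraries and bars for the mean ± SD of the 3 libraries of each group. Mean JAG1 fell from 195.9 CPM in wild type to 94.5 in clone 1 and 66.9 in clone 2, and mean SPARC from 95.8 CPM to 4.95 and 3.98.

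Clone 1 had almost no transcript of several genes that wild-type cells expressed. PCSK1N, which encodes a peptide precursor of the secretory pathway, had 0 counts over the 3 clone 1 libraries against 1161 in wild type, and was at least 352-fold lower. CST7, which encodes cystatin F, an inhibitor of lysosomal cysteine proteases, had 0 counts against 1008 and was at least 306-fold lower. CNTN1, a neuronal cell adhesion molecule, fell from 17.2 ± 5.17 to 0.149 ± 0.121 CPM (n = 3 each, log2 fold change −6.75, SE 0.37, adjusted p = 1.68e-08). In the other direction MAGEB2, a cancer-testis gene on the X chromosome, rose from 2.14 ± 0.215 to 44.3 ± 5.98 CPM (n = 3 each, log2 fold change 4.36, SE 0.21, adjusted p = 1.73e-08).

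The rest of the 8 largest named decreases in clone 1 left only 2 or 3 counts over its 3 libraries. PKIA, an inhibitor of protein kinase A, had a wild type to clone 1 ratio of 474 (95% counting interval 131 to 3920), and PDE1C, a cyclic nucleotide phosphodiesterase, one of 254 (86.7 to 1240). TLR4, the receptor for bacterial lipopolysaccharide, had a ratio of 144 (48.9 to 699), and COCH, which encodes cochlin, one of 118 (40 to 574). The ratio of MAGEA6 was 243 (67.0 to 2010), but genes of the MAGEA, XAGE and SSX families have near-identical copies, so their counts are uncertain. Adjusted p for these decreases was at most 2.86e-05 by edgeR. The other named increases were LILRB1, an inhibitory receptor of leukocytes (log2 fold change 3.37), ANXA10, an annexin (3.02), CT83, a cancer-testis gene (2.50), and HSD11B1, the enzyme that makes active cortisol from cortisone (2.41). MYH15 (2.09), XAGE2 (1.90) and NAA11 (1.72) rose as well, and adjusted p for these increases was at most 0.00574. All 16 of these calls held when any 1 of the 9 libraries was left out.

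In total, 933 of 16921 genes differed between clone 1 and wild type at an adjusted p under 0.05 in edgeR, 239 higher and 694 lower, and 101 and 250 of them by more than 2-fold. The 3 libraries of each group did not overlap for 29.64% of all tested genes, where chance gives 10%. Higher genes made up 25.6% of the calls, and 41.1% (342 of 833) after a correction for GC content and length that was chosen after the data were seen. The count fell to 200 without clone 1 replicate 3, 330 without clone 1 replicate 2, 383 without clone 1 replicate 1, 278 without wild-type replicate 3 and 436 without wild-type replicate 2.

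Of 20 tested Notch target genes, 4 fell in clone 1 and 16 did not pass, and 7 fell when adjusted over the list alone. HES1, a transcriptional repressor induced by Notch, fell from 41.3 ± 1.82 to 24.2 ± 1.03 CPM (n = 3 each, log2 fold change −0.77, SE 0.17, adjusted p = 0.0157). BHLHE40 (−0.83), SNAI2 (−0.85) and GATA3 (−0.66), which also encode transcription factors, fell as well, but after the GC and length correction BHLHE40 and GATA3 lost their calls (adjusted p = 0.0573 and 0.0629). GATA3 kept its call in 1 of 9 fits with a library left out (adjusted p of up to 0.149). The list as a whole was lower (median −0.50, camera adjusted p = 0.00671; adjusted p = 0.235 with an estimated correlation). Of 26 Notch receptors, ligands and processing genes, 3 fell in clone 1 and 23 did not pass, with the same 3 adjusted over the list alone. These were NEURL1B, a ubiquitin ligase for Notch ligands (−0.69), MAML2, a coactivator of Notch transcription (−0.84), and NUMBL (−0.71). That list missed the threshold (median −0.12, camera adjusted p = 0.0569) but passed fry (0.00287). The receptors did not pass the test, with log2 fold changes of −0.17 for NOTCH1 (adjusted p = 0.601), −0.27 for NOTCH2 (0.331), −0.42 for NOTCH3 (0.346) and 0.01 for NOTCH4 (0.994). The remaining ligand genes JAG2 (−0.01, adjusted p = 0.987) and DLL1 (−0.58, 0.381) did not pass either.

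Mesenchymal genes were lower in clone 1. Of 20 tested mesenchymal genes and regulators of the epithelial-mesenchymal transition (EMT), 4 fell and 16 did not pass, and 9 fell adjusted over the list alone. SPARC, a secreted matrix glycoprotein, fell by 4.27 on the log2 scale (SE 0.28, adjusted p = 2.91e-07). FN1, which encodes fibronectin, fell from 980 ± 259 to 333 ± 71.2 CPM (n = 3 each, log2 fold change −1.56, SE 0.29, adjusted p = 0.00796). ZEB2 (−0.94) and SNAI2 (−0.85), transcription factors that repress E-cadherin, fell too (list median −0.49, camera adjusted p = 8.65e-05; adjusted p = 0.235 with an estimated correlation). In the list of 20 epithelial genes, the keratins KRT7 (−1.12), KRT8 (−0.70) and KRT18 (−0.67, lost after the GC and length correction, adjusted p = 0.0596) fell and LAMB3, a chain of laminin-332, rose (0.80), and the list missed the threshold (camera adjusted p = 0.126). Adjusted over the list alone, 7 epithelial genes fell and 2 rose, and the list median was −0.31, so lower values were not particular to mesenchymal genes. Of 36 matrix and protease genes, LAMA4 (−1.47), COL12A1 (−0.84) and LOXL2 (−0.60) fell and LAMA3 rose (0.68), with 6 lower and 2 higher adjusted over the list alone. As a list they were lower (median −0.44, camera adjusted p = 0.0158; adjusted p = 0.632 with an estimated correlation, and 0.0596 after the GC and length correction). Targets of TGF-beta and YAP were lower with 4 of 28 members down, TGFB2 (−1.04), INHBA (−1.88), LATS2 (−0.70) and AMOTL2 (−0.67), against 6 lower and 1 higher adjusted over the list alone. Their median was −0.14 (camera adjusted p = 0.0327; adjusted p = 0.370 with an estimated correlation, and 0.0892 after the GC and length correction).

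Among 14 genes of lymph node homing and lymphangiogenesis, the chemokine receptor CXCR4 rose in clone 1 from 15.9 ± 3.01 to 33.5 ± 4.84 CPM (n = 3 each, log2 fold change 1.08, SE 0.19, adjusted p = 0.00467), and the growth factor PDGFB fell (−1.41). VEGFC, a lymphatic growth factor, had a log2 fold change of 0.47 that did not pass over all genes (adjusted p = 0.0664). The list was higher, with 4 higher and 1 lower adjusted over the list alone (median 0.26, camera adjusted p = 0.0327; adjusted p = 0.370 with an estimated correlation, and 0.0596 after the GC and length correction). Inflammatory and NF-kappaB genes were lower, with 3 of 27 members down (5 adjusted over the list alone). These were ICAM1, an adhesion molecule for leukocytes (−3.37), NFKB1 (−0.80) and SAA1 (−2.18), for a list median of −0.39 (camera adjusted p = 0.00671; adjusted p = 0.370 with an estimated correlation). Interferon-stimulated genes were lower with 7 of 42 members down (10 adjusted over the list alone), among them IFI27 (−1.64) and BST2 (−1.38), which tethers virus particles to the cell. Their median was −0.26 (camera adjusted p = 0.00638; adjusted p = 0.370 with an estimated correlation). The MHC class II invariant chain gene CD74 fell (−1.29), while the MHC class I list with 0 of 16 members called by edgeR (2 lower adjusted over the list alone, and 2 at an unadjusted p under 0.05) and the class II list with 1 of 10 missed the threshold (camera adjusted p = 0.129 and 0.0805, the latter 0.0465 with the replicate block).

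Genes of DNA replication were lower in clone 1, with MCM2, a subunit of the replicative helicase (−0.79), and GINS1 (−1.08) down among 31 members and 8 down adjusted over the list alone. Their median was −0.27 (camera adjusted p = 0.0127; adjusted p = 0.644 with an estimated correlation). TPX2, a spindle assembly factor, fell (−0.79), but the list of 30 mitotic genes missed the threshold (camera adjusted p = 0.120). Genes of the unfolded protein and amino acid responses were lower with 4 of 27 members down, SLC7A11, the cystine transporter (−1.15), PHGDH (−0.69), SHMT2 (−0.57, lost after the GC and length correction, adjusted p = 0.0639) and CEBPB (−0.66). Their median was −0.17 (camera adjusted p = 0.0164; adjusted p = 0.632 with an estimated correlation), and the same 4 were called adjusted over the list alone. Cholesterol biosynthesis genes were lower as a list of 24 (median −0.39, camera adjusted p = 0.0242; adjusted p = 0.644 with an estimated correlation), with 0 members called by edgeR over all genes or over the list alone (4 lower at an unadjusted p under 0.05), and FDPS nearest at −0.57 (adjusted p = 0.0747). Lists of p53 targets (PHLDA3 −1.89), stem cell markers (ALDH1A3 −1.15), hypoxia and glycolysis genes (BNIP3 0.93) and growth factors (WNT7B 0.86, HBEGF 0.57 and WNT5A −0.99) had these members called and missed the threshold as lists, with camera adjusted p of 0.650, 0.650, 0.914 and 0.894. Camera's direction was down for stem cell markers with a median of 0.03, and up for hypoxia genes with a median of −0.11.

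Signs of RNA composition moved with these groups. Mitochondrially encoded mRNA made up 2.62 ± 1.01% of counts in wild type and 3.60 ± 1.31% in clone 1 (SD, n = 3 each), with 0 of 13 genes called by edgeR (1 higher at an unadjusted p under 0.05) but a higher list median of 0.49. The camera adjusted p was 0.00671 (adjusted p = 0.632 with an estimated correlation, and 0.144 after the GC and length correction). Ribosomal protein genes had a median of 0.17, with RPL10 (0.71) called of 51 over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00671; adjusted p = 0.644 with an estimated correlation). Basal and myoepithelial genes were lower (median −1.13, camera adjusted p = 0.0395; adjusted p = 0.335 with an estimated correlation), with MYLK (−1.12) and OXTR (−1.74) down and KRT15 up (1.02) of 8. Luminal markers had SPDEF up (1.07) and GATA3 down, and they missed the threshold, as did blood and endothelial markers and histones (camera adjusted p = 0.191, 0.684 and 0.169). The histone genes HIST1H2BK (−1.12) and HIST1H2AC (−0.84) fell of 12. Of the list members the naming rule selected, SPARC, KRT7, CXCR4, ICAM1, IFI27, TGFB2, INHBA, GINS1, PHLDA3, SLC7A11, WNT7B, MYLK and HIST1H2BK kept their clone 1 calls without any 1 library. Each other one lost its call without clone 1 replicate 3, with adjusted p of up to 0.212 in leave-one-out fits.

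Clone 2 also had near-absent transcripts, and 3 of its 8 largest named decreases (PKIA, MAGEA6 and TLR4) were among the 8 of clone 1. EYA1, a transcriptional coactivator, had 0 counts over its 3 libraries against 360 in wild type, and was at least 108-fold lower. DMD, the dystrophin gene, fell from 6.11 ± 1.14 to 0.125 ± 0.108 CPM (n = 3 each, log2 fold change −5.58, SE 0.49, adjusted p = 6.62e-06). TLR4 fell by 5.84 on the log2 scale (SE 0.65, adjusted p = 9.45e-05). SSX1, a cancer-testis gene whose counts are uncertain, rose from 0.598 ± 0.0786 to 5.88 ± 3.04 CPM (n = 3 each, log2 fold change 3.28, SE 0.47, adjusted p = 0.00134). COBL, an actin nucleator, rose from 4.17 ± 1.30 to 15.1 ± 5.50 CPM (n = 3 each, log2 fold change 1.85, SE 0.33, adjusted p = 0.00492).

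The rest of the 8 largest named decreases in clone 2 were those of PKIA (2 counts, ratio 470, 95% counting interval 130 to 3890), DDX53 (2 counts, ratio 155, 42.5 to 1280), MAGEA6 (0 counts, at least 161-fold), MAGEA3 (log2 fold change −5.99) and POSTN, which encodes periostin (−6.69, SE 1.54, adjusted p = 0.0372). Outside those 8, COL4A5 and NAA11 also had 0 counts in clone 2 (at least 95.7-fold and 80.7-fold lower). Wild-type POSTN varied widely between libraries (7.75 ± 10.1 CPM, n = 3), and its call was lost without wild-type replicate 2 or any 1 clone 2 library, with adjusted p of up to 0.237, and after the GC and length correction (adjusted p = 0.0537). The other named increases were ESM1, a secreted proteoglycan of endothelial cells (2.68), JAKMIP1 (1.87), MUSK, a receptor kinase of the neuromuscular junction (1.74), the cytokine IL24 (1.70), CNKSR2 (1.64) and PROSER2 (1.48), with adjusted p of at most 0.0213. Leaving out clone 2 replicate 3 ended the calls of ESM1, JAKMIP1, MUSK and PROSER2, leaving out wild-type replicate 1 those of ESM1, MUSK, IL24 and PROSER2, and leaving out wild-type replicate 2 those of MUSK, CNKSR2 and PROSER2, with adjusted p of up to 0.112.

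In total, 1008 of 16921 genes differed between clone 2 and wild type at an adjusted p under 0.05 in edgeR, 543 higher and 465 lower, but 65 higher and 295 lower by more than 2-fold. Lower genes were the majority with RLE size factors (470 higher, 488 lower), no filter on low counts (687 and 976), a fit of the 6 libraries (160 and 256) and the mitochondrial covariate (11 and 69). They were so too without wild-type replicate 1 (83 and 214) or 2 (62 and 176), clone 1 replicate 1 (436 and 446), 2 (251 and 347) or 3 (355 and 362), and clone 2 replicate 2 (483 and 730) or 3 (75 and 162). Their libraries did not overlap for 25.94% of tested genes, where chance gives 10%. Same-numbered wild-type and clone 2 libraries resembled each other most, which does not establish that they were paired. With the replicate number as a block the count was 2699 (1528 higher, 1171 lower), among them all 1008. The count fell to 237 without clone 2 replicate 3, 238 without wild-type replicate 2, 297 without wild-type replicate 1 and 598 without clone 1 replicate 2, and rose to 1584 without wild-type replicate 3.

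Interferon-stimulated genes were lower in clone 2. Of 42 members, 8 fell and 1 rose, and 23 fell and 2 rose adjusted over the list alone. IFI27 fell from 16.2 ± 3.33 to 1.98 ± 0.701 CPM (n = 3 each, log2 fold change −3.05, SE 0.28, adjusted p = 1.14e-05). OASL, an antiviral protein related to the oligoadenylate synthetases (−3.53), and BST2 (−1.96) fell, and DDX58, which encodes the RNA sensor RIG-I, rose (0.94). The list median was −0.78 (camera adjusted p = 4.44e-09; adjusted p = 0.329 with an estimated correlation). MHC class II genes were lower with 3 of 10 members down (5 adjusted over the list alone), HLA-DPA1 (−2.90), HLA-DMA (−1.39) and CIITA, the transactivator of class II genes (−1.08). Their median was −1.08 (camera adjusted p = 0.000137; adjusted p = 0.329 with an estimated correlation), and HLA counts are uncertain because the genes are polymorphic and alike. In the MHC class I list ERAP2, a peptidase that trims antigens (−1.13), and PSMB9, a subunit of the immunoproteasome (−1.04), fell of 16, or 4 adjusted over the list alone (median −0.15, camera adjusted p = 0.0404; adjusted p = 0.682 with an estimated correlation). Inflammatory genes were lower with IL1B (−1.94) and ICAM1 (−1.68) down and IL24 up of 27, or 5 lower and 1 higher adjusted over the list alone (median −0.36, camera adjusted p = 0.0172; adjusted p = 0.442 with an estimated correlation).

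Genes of DNA replication were higher in clone 2. Of 31 members, 6 rose and 25 did not pass, and 14 rose and 1 fell adjusted over the list alone. UHRF1, a cofactor of maintenance DNA methylation, rose from 174 ± 30.9 to 291 ± 24.1 CPM (n = 3 each, log2 fold change 0.74, SE 0.16, adjusted p = 0.0162). MCM2 (0.72) and CLSPN, a replication checkpoint protein (0.69), rose as well (list median 0.36, camera adjusted p = 6.28e-05; adjusted p = 0.563 with an estimated correlation). TPX2 rose (0.67), as the 1 member called of 30 mitotic genes, which missed the threshold as a list (camera adjusted p = 0.126) but passed after the GC and length correction (0.0389).

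Notch genes went both ways in clone 2. Of 20 Notch targets, HES1 (−0.78) and HES4 (−1.35) fell while SOX9 (0.62), CDKN1A, a cell cycle inhibitor (0.58), and CCND1, cyclin D1 (0.58), rose, with 5 lower and 3 higher adjusted over the list alone (median −0.06, camera adjusted p = 0.826). RBPJ, the DNA-binding partner of the Notch intracellular domain, rose from 213 ± 46.9 to 429 ± 23.0 CPM (n = 3 each, log2 fold change 1.01, SE 0.17, adjusted p = 0.00260). MAML1 rose (0.48) and POGLUT1, which glycosylates Notch receptors, fell (−0.64) among 26 receptors, ligands and processing genes, or 2 higher and 2 lower adjusted over the list alone (median 0.01, camera adjusted p = 0.826). MAML1 lost its call with RLE size factors (adjusted p = 0.0511) and after the GC and length correction (0.0826), and CCND1 with RLE size factors (0.0513). Log2 fold changes that did not pass were −0.01 for NOTCH1 (adjusted p = 0.979), 0.14 for NOTCH2 (0.625), −0.67 for NOTCH3 (0.126), −0.01 for NOTCH4 (0.994), −0.29 for JAG2 (0.243) and −0.70 for DLL1 (0.273).

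Matrix genes were lower in clone 2, with LUM, the proteoglycan lumican (−4.86), POSTN (−6.69), COL3A1 (−2.16) and LAMA3 (−0.65) down of 36 members, or 7 lower and 1 higher adjusted over the list alone. Their median was −0.32 (camera adjusted p = 0.00687; adjusted p = 0.682 with an estimated correlation). In the list of 20 mesenchymal and EMT genes SPARC (−4.60) and S100A4, a calcium-binding protein (−2.43), fell and VIM, vimentin (0.69), CDH11 (0.68) and LOX (0.53) rose, with a median of 0.04, a mean of −0.18 and camera adjusted p of 0.561. PDPN, the lymphatic glycoprotein podoplanin, rose from 27.4 ± 3.24 to 62.0 ± 15.1 CPM (n = 3 each, log2 fold change 1.18, SE 0.17, adjusted p = 0.00109), as the 1 gene called of 14 in the homing list. That list missed the threshold (camera adjusted p = 0.599), and CXCR4 did not pass over all genes (0.64, adjusted p = 0.0575). Of 28 TGF-beta and YAP targets, CTGF rose (0.90), and the list passed camera only with the replicate block (adjusted p = 0.0689 without it, 0.0128 with it, median 0.18). Cholesterol biosynthesis genes passed as a lower list only with the block (0.191 without it, 0.00990 with it, median −0.12). LAMB3 (0.89) was the 1 epithelial gene called, and the list missed the threshold (camera adjusted p = 0.547).

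The growth factor genes EREG (−1.56), AREG (−1.68) and BTC (−2.01), ligands of the EGF receptor family, fell among 26 members (camera adjusted p = 0.121, fry 0.0310). In the list of 33 hypoxia and glycolysis genes HK2 (0.90), HK1 (0.72) and GPI (0.67), enzymes of early glycolysis, rose, while CA9, a carbonic anhydrase (−1.72), and ANKRD37 (−0.89) fell (camera adjusted p = 0.0689). SLC7A11 fell (−1.30) in the list of unfolded protein and amino acid responses (camera adjusted p = 0.953). PMAIP1 fell (−0.85) and CDKN1A rose among p53 targets (camera adjusted p = 0.840), and SOX9 was the 1 stem cell marker called (camera adjusted p = 0.599). Camera's direction was up for stem cell markers with a median of −0.01. Mitochondrially encoded mRNA made up 1.21 ± 0.506% of counts (SD, n = 3) against 2.62 ± 1.01% in wild type, and fell as a list with 1 of 13 genes called by edgeR, MT-CO1 (−1.17, lost after the GC and length correction, adjusted p = 0.0644), and 10 adjusted over the list alone. The list median was −0.94 (camera adjusted p = 4.18e-06; adjusted p = 0.552 with an estimated correlation). Replication-dependent histones HIST1H2BK (−0.83), HIST1H1C (−1.06) and HIST1H2AC (−1.17) fell of 12 (list median −0.29, camera adjusted p = 0.0126; adjusted p = 0.442 with an estimated correlation, and 0.153 after the GC and length correction). Luminal markers (ANKRD30A −1.97), basal markers (KRT15 0.86), blood and endothelial markers (CD14 −2.92) and 51 ribosomal protein genes missed the threshold as lists, with camera adjusted p of 0.126, 0.561, 0.130 and 0.624 (blood and endothelial markers passed fry at 0.0195).

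With the share of mitochondrial mRNA as a covariate, a setting added after the data were seen, 80 genes were called in clone 2 in place of 1008. For those 1008 the median absolute log2 fold change went from 0.78 to 0.63 and its SE from 0.18 to 0.22, with 100% of signs kept. Clone 2 libraries also detected fewer genes, 21364 ± 1444 against 23590 ± 688 in wild type (SD, n = 3 each). Of the list members the naming rule selected, RBPJ, S100A4, LUM, SPARC, PDPN, IFI27, OASL, BST2, DDX58, HLA-DPA1, PMAIP1, SLC7A11, EREG, ANKRD30A and the 3 histones kept their clone 2 calls without any 1 library. IL24 lost its call without wild-type replicate 1 and LAMB3 and CD14 without wild-type replicate 2, and each other one lost its call without clone 2 replicate 3, with adjusted p of up to 0.244. LAMA3, SAA1, HBEGF, COL3A1, VIM, CDH11, LOX, CTGF, BTC, HK1 and ANKRD37 lie outside the naming rule and were named after their values were seen, because few members of their lists were called.

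**Figure D2:**
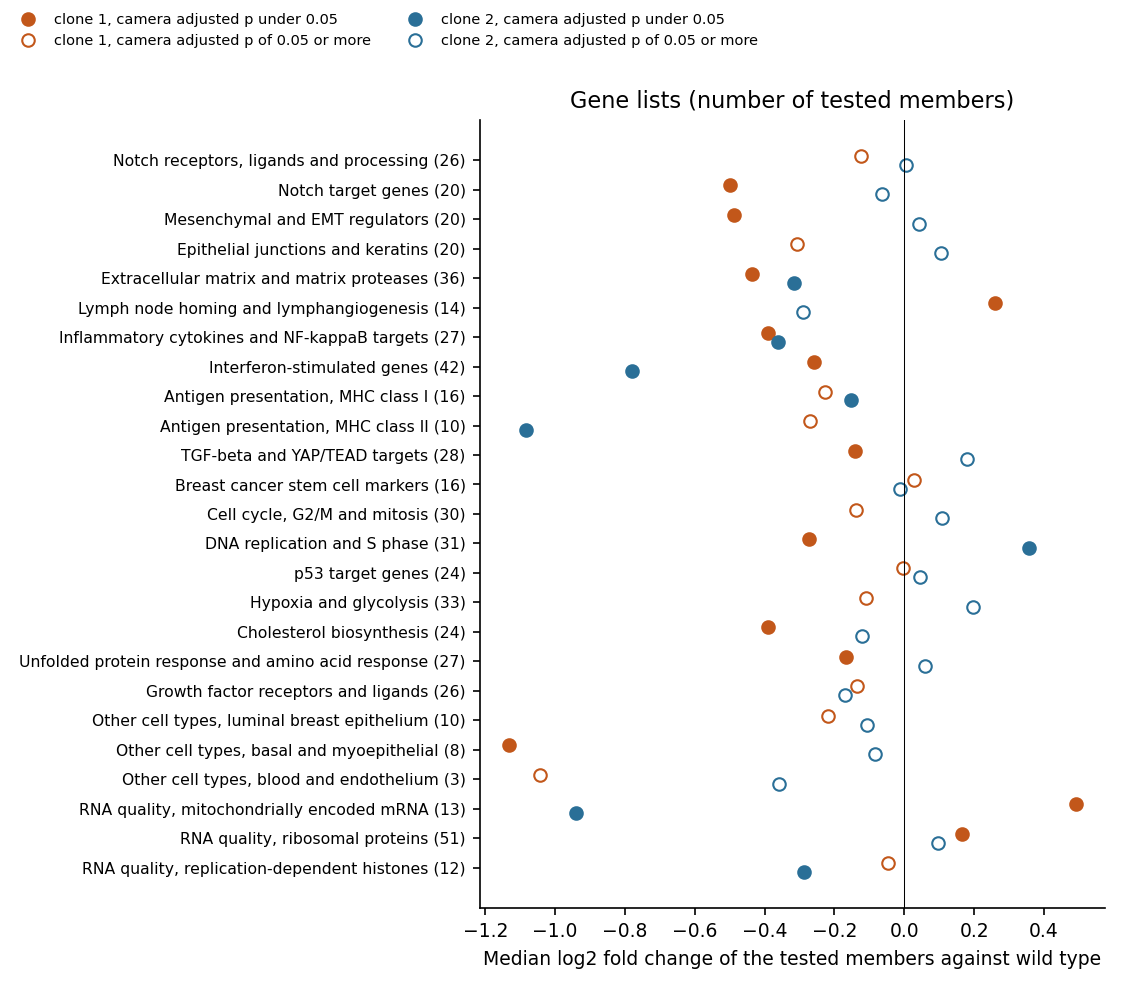
Median log2 fold change against wild type (horizontal axis) of the tested members of each of the 25 gene lists, with clone 1 in orange and clone 2 in blue, filled where camera's adjusted p with a preset correlation of 0.01 was under 0.05. Camera called 13 lists in clone 1 and 8 in clone 2, and 0 of them in either clone passed with an estimated correlation.

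SPARC had a large decrease in both clones. It fell from 95.8 ± 34.5 CPM in wild type to 4.95 ± 1.55 in clone 1 and 3.98 ± 0.847 in clone 2 (n = 3 each, log2 fold changes −4.27 and −4.60, SE 0.28 each, adjusted p = 2.91e-07 and 6.49e-07). LAMA5, a laminin chain (−1.84 and −3.10), BMP5, a growth factor of the TGF-beta family (−3.07 and −1.92), RNASE1, a secreted ribonuclease (−3.41 and −2.68), SCG2, a protein of secretory granules (−1.82 and −2.06), and VIPR1, a neuropeptide receptor (−1.84 and −2.87), fell in both. KYNU, kynureninase of tryptophan breakdown (−4.95 and −3.95), and POU3F2, a neural transcription factor (−4.82 and −3.70), fell with them, as did PKIA, TLR4, MAGEA6 and MAGEA3. Increases common to both were smaller, among them MAST4 (0.87 and 0.90), KRT15 (1.02 and 0.86), ZDHHC21, a palmitoyl transferase (0.80 and 1.45), and LAMB3 (0.80 and 0.89).

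ZNF185 (0.88 and 0.71), ST3GAL1, a sialyltransferase (0.66 and 0.69), CCDC69 (0.84 and 0.62) and ABLIM3 (0.51 and 0.48) rose in both clones as well. HES1, SLC7A11, ICAM1, IFI27, BST2, HIST1H2BK and HIST1H2AC were list members called lower in both clones. In all, 103 genes were called in the same direction in both clones, 12 higher and 91 lower, against 7.7 and 19.1 for independent lists of these sizes. Another 118 genes were called in opposite directions (28.8 for independent lists), 90 of them lower in clone 1 and higher in clone 2.

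Both comparisons use the same 3 wild-type libraries, too few to split, so part of the excess may come from sharing them. In 20 simulated pairs of unchanged groups whose mean carried the error of the wild-type mean, edgeR gave 0 shared genes and at most 197 at an unadjusted p under 0.05, against 393 observed. In 20 built from the residuals of the real libraries it gave 0 and at most 1676. The simulated groups had almost no calls to share, so these counts of 0 exclude nothing. Log2 fold changes of the clones correlated across genes, which are not independent replicates, at 0.106, against a mean of 0.508 and 0.480 in the 2 kinds of simulation. Their covariance of 0.0573 also lay below the simulated means of 0.0847 (0.0800 to 0.0888) and 0.129 (0.0204 to 0.4355, 9 of 20 below the observed value), by differences of −0.0274 and −0.0718. No covariance beyond that of shared controls was seen over all genes, but a pairing of wild-type with clone 2 libraries, if there was one, would lower the covariance. These values therefore do not exclude a shared change. With the mitochondrial share as a covariate the shared count was 27, 1 higher and 26 lower. Of the 12 decreases the naming rule selected, 11 kept their clone 1 call and 10 their clone 2 call without any 1 library, while 1 of its 10 increases did so in each clone. LAMA5 lost its clone 1 call without wild-type replicate 2 or 3, any 1 clone 1 library or clone 2 replicate 3 (adjusted p of up to 0.156), and BMP5 and LAMA5 lost their clone 2 calls without clone 2 replicate 3. The increases lost calls in clone 1 without clone 1 replicate 3, except CCDC69, and in clone 2 without wild-type replicate 2, except ZDHHC21, with adjusted p of up to 0.188. The shared count fell to 45 without wild-type replicate 2 or clone 1 replicate 3, 55 without clone 2 replicate 3, 57 without clone 1 replicate 2 and 65 without wild-type replicate 1 or clone 1 replicate 1.

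**Figure D3:**
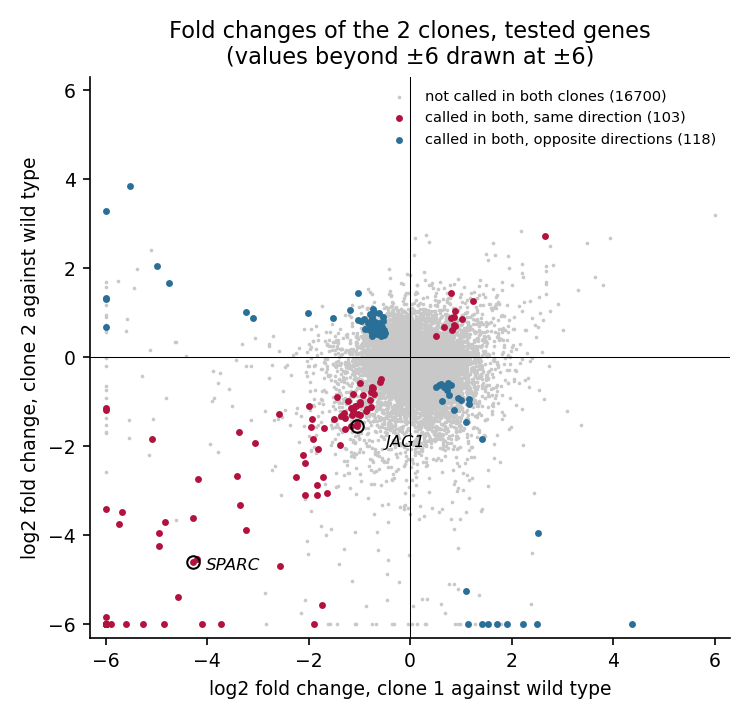
Log2 fold change against wild type in clone 1 (horizontal axis) and clone 2 (vertical axis) for the 16921 tested genes, where values beyond the axis limits are drawn at the limit and fitted values of genes near 0 counts are not estimates of size. Red points are the 103 genes called in the same direction in both clones, blue points the 118 called in opposite directions, and JAG1 and SPARC are circled.

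More genes were called between the clones, 5733, than between either clone and wild type, but with the mitochondrial share as a covariate clone 1 against wild type had more (687 against 391). CNTN1 was 8.09 higher on the log2 scale in clone 2 than in clone 1 (SE 0.36, adjusted p = 7.09e-10), at 43.6 ± 1.71 against 0.149 ± 0.121 CPM (n = 3 each), and it was higher in clone 2 and lower in clone 1 than in wild type. PCSK1N, PTCHD1, CST7 and SSX1 had 0 counts in clone 1 and were at least 567-fold, 140-fold, 139-fold and 109-fold higher in clone 2. MAGEB2, NAA11, CT83, COL4A5, a collagen IV chain, and XAGE2 had 0 counts in clone 2 and were at least 856-fold, 263-fold, 230-fold, 212-fold and 205-fold higher in clone 1. Each of these 5 was called higher in clone 1 and lower in clone 2 against wild type, where clone 2 was at least 41.5-fold (MAGEB2 and CT83), 80.7-fold (NAA11), 95.7-fold (COL4A5) and 54.5-fold (XAGE2) lower. COL4A5 lost its clone 1 call without wild-type replicate 2 or 3 or any 1 clone 1 library (adjusted p of up to 0.115).

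Genes of DNA replication were higher in clone 2 than in clone 1 for 20 of 31 members and lower for 2, or 23 and 2 adjusted over the list alone (median 0.55, camera adjusted p = 1.86e-05; adjusted p = 0.672 with an estimated correlation). MCM2 stood at 174 ± 22.4 CPM in clone 2, 60.7 ± 10.6 in clone 1 and 105 ± 20.98 in wild type (n = 3 each, log2 difference between the clones 1.52, SE 0.17, adjusted p = 3.03e-05). TGF-beta and YAP targets were higher for 10 of 28 members and lower for 1, or 13 and 1 adjusted over the list alone (median 0.49, camera adjusted p = 0.0200; adjusted p = 0.667 with an estimated correlation), with AMOTL2 at 1.06 and LATS2 at 0.83. Mitochondrially encoded mRNA was lower for 12 of 13 members, and all 13 adjusted over the list alone (median −1.43, camera adjusted p = 2.31e-06; adjusted p = 0.667 with an estimated correlation). Notch targets had 7 of 20 members higher and 13 that did not pass, including SOX9 and CCND1 (1.10 each), and missed the threshold as a list (camera adjusted p = 0.171) but passed fry (0.00466). HES1 did not pass between the clones (−0.02, SE 0.17, adjusted p = 0.949).

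By edgeR, 5733 of 16921 genes differed between the clones, 3353 higher and 2380 lower in clone 2, and the libraries did not overlap for 47.38% of genes, where chance gives 10%. Wild type lay between the clones for 5200 of the 5733, a share that selecting genes by the clone difference raises. The count was 3639 without clone 2 replicate 3, 3778 without clone 1 replicate 3, and 391 with the mitochondrial share as a covariate. CNTN1, the 9 genes with 0 counts in a clone, MCM2, AMOTL2, LATS2, SOX9 and CCND1 kept their difference between the clones with any 1 library left out.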

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

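Chosen only after the result was seen were the tests of library position against the mitochondrial share, of the genes on the centromere side of JAG1, and of fold sizes with the mitochondrial covariate, the leaving out of libraries for single genes between the clones, the simulations with a shared error of the wild-type mean and their genes over 2-fold apart, as well as the covariate and the GC and length correction themselves. Groups of 3 libraries are too small for a test of single outlying libraries, so the results below are differences between the 2 clones, each by the test of clone 2 against clone 1.

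Between the clones 5733 genes differed, and JAG1 itself was lower in clone 2 (log2 difference −0.50, lower in 3 of 3 libraries; the call was lost without clone 1 replicate 1 or 3 or clone 2 replicate 3, adjusted p of up to 0.172). As lists, targets of TGF-beta and YAP (camera adjusted p = 0.0200, median 0.49) and genes of DNA replication (1.86e-05, median 0.55) were higher in clone 2, and mitochondrially encoded mRNA was lower (2.31e-06, median −1.43), with adjusted p of 0.667, 0.672 and 0.667 with an estimated correlation. Of the genes named for clone 1, 8 of 8 increases and 5 of 8 decreases differed between the clones, and of those named for clone 2, 8 of 8 increases and 5 of 8 decreases. Of the genes named for both clones, 1 of 10 increases (ZDHHC21) and 3 of 12 decreases (MAGEA3, VIPR1 and BMP5) differed in size between the clones, although both clones moved the same way against wild type. Of these 4, MAGEA3 kept its difference with any 1 library left out, and each of the others lost it without clone 1 replicate 3, among other clone libraries (adjusted p of up to 0.158). Named genes called in opposite directions in the clones, with no overlap between the 3 libraries of each clone, were CNTN1 (adjusted p = 7.09e-10), PCSK1N (8.48e-10), SSX1 (8.26e-06), MCM2 (3.03e-05, log2 difference 1.52) and TPX2 (3.89e-05, 1.45), higher in clone 2. The clone 2 increase of PCSK1N (0.68, adjusted p = 0.0442) kept its call in 1 of 9 fits with a library left out and lost it with RLE size factors (adjusted p of up to 0.218). MCM2 and TPX2 each lost a call in at least 1 clone without wild-type replicate 1, 2 or 3, clone 1 replicate 2 or 3 or clone 2 replicate 3, and TPX2 also without clone 1 replicate 1 (adjusted p of up to 0.164). COL4A5 lost its clone 1 call as given above. MAGEB2 (7.09e-10), NAA11 (4.83e-08), COL4A5 (1.04e-07), CT83 (1.94e-07) and XAGE2 (2.40e-07) were lower in clone 2, where each had 0 counts.

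Other splits of the compared libraries were counted for each comparison, with the 6 libraries fitted alone. For clone 1 against wild type, 1 of 10 splits, the real one, gave 1296 genes and the highest other gave 1. For clone 2 against wild type, 1 of 10 gave 416 and the highest other gave 0 by edgeR (1544 at an unadjusted p under 0.05, against 3442). The 3 other splits that part each same-numbered pair gave at most 92 at an unadjusted p under 0.05. Between the clones, 1 of 10 gave 5554 and the highest other gave 0 by edgeR (591 at an unadjusted p under 0.05, against 7200). In these 3 cases 10 splits are too few for a share under 0.05. For genes called in both clones, 2 of 100 drawn splits of the 9 libraries into a reference and 2 arms gave as many, the real one with 103 included. But 96 of the others, which mix the lines, gave 0 by edgeR, and at an unadjusted p under 0.05, 15 of the 100 gave at least the 393 genes of the real split, up to 3332, so chance is not excluded by these splits. The highest other split, with 133, had the clone 2 libraries as the reference and mixed wild type and clone 1 in the arms, and the next gave 8.

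The difference of 5733 genes between the clones was weighed against bias and a gradient between libraries. After the correction for GC content and length, 5531 genes differed, 96.5% of the count, which argues against such a bias as the whole cause. Within groups, a library's position along the clone difference followed its log2 mitochondrial share (Pearson's r = −0.803, p = 0.0417 over all 216 permutations; Spearman's rho = −0.750, p = 0.0509), so a gradient between libraries may contribute. Pearson's r was −0.835 without clone 2 replicate 2 and clone 1 replicate 1. In these, the deviation of the log2 mitochondrial share from the group mean lay farthest from the median deviation. With that share as a covariate 6.8% of the count was left, which met the bound set for the share as the whole cause, but the median absolute log2 fold change of the 5733 genes went from 0.81 to 0.59 while its SE went from 0.179 to 0.272, and 96.9% kept their sign. The share as whole cause and the clones cannot be told apart, since 67.2% of the share's variance lay between groups and calls ended through a wider error as well as smaller folds, and a biological difference between the clones stays open, untested.

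The 103 genes called in both clones were weighed against the error of the wild-type mean, which both comparisons share: 40 of them had every wild-type library over 2-fold from all 6 knockout libraries, against at most 5 and 20 genes in the 2 kinds of simulation of unchanged groups. That is more than in any simulation, but under the margin of 5 times set for excluding the shared libraries as a source. PKIA (16.2 ± 1.47 CPM in wild type, 2 counts in each clone) and TLR4 (7.35 ± 0.806 CPM, 3 and 7 counts) lay far outside that error, while for the count as a whole it cannot be told apart from a shared change, since simulated groups had almost no calls to share (at most 0 shared genes in edgeR, and up to 1676 at an unadjusted p under 0.05 against 393 observed). With clone 1 or clone 2 as the reference in place of wild type, 745 and 824 genes were called the same way, so the count with wild type was 0.125 of the higher one. That met the bound set beforehand for lines that diverged independently of JAG1, wild type being no farther from the others than each clone is. But the counts with a clone as the reference draw on the 5733 genes that differed between the clones. A low ratio can thus arise with or without a shared change in the 103 genes, and it does not decide between them. Loss of JAG1 stays open for any of the 103, since each clone is 1 line and no rescue was among the samples. Both clones also went through Cas9 treatment and growth from a single cell. Unless the wild-type cells did too, effects of these steps cannot be told apart from loss of JAG1.

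Runs of neighbouring genes moved together, in 8 of 663 windows of 50 genes in clone 1 and 22 of 663 in clone 2, a pattern that copy number differences between the lines may explain. Whether a named gene lies in such a run was not weighed above, so its fold change may include a shift of its neighbours. In clone 2 the largest shift was on chromosome 9 from 14521 to 41218410 (median log2 shift 0.84, 90% of genes the same way), with a decrease on chromosome 10 from 110898730 to 133561220 (−0.46, 84%). In clone 1 the end of X from 142202345 to 156025710 was higher (0.70, 94%; not called with windows of 100 genes) and chromosome 5 from 154712902 to 176659054 lower (−0.48, 86%), and DNA copy number was not analysed here, so regional regulation stays open. Loss of the chromosome end beyond the Cas9 site predicted a median below −0.3 for genes from JAG1 to the end of 20p. Clone 2 stood at −0.142 (95% interval −0.212 to −0.060), and at −0.185 (−0.264 to −0.081) for genes with a mean of at least 5 CPM. Both intervals lay above −0.3, which argues against a loss of that size. But the median at 5 CPM missed the bound set beforehand for no loss. It lay below the 50 genes on the centromere side (−0.101, and −0.146 without the CPM limit), so a smaller shift stays open. Clone 1 stood at −0.253 (−0.338 to −0.168), but the 50 genes on the centromere side stood at −0.293 and all 445 genes of chromosome 20 at −0.284, so no step lay at JAG1, which argues against a loss that begins there.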

How the results depend on the processing

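The GC and length correction, the same with the replicate block, and the mitochondrial covariate were chosen only after the data were seen. JAG1 kept its direction and its call in both clones under the 14 settings read out for it, with log2 fold changes of −1.18 to −0.86 in clone 1 (largest adjusted p = 0.0309) and −1.70 to −1.35 in clone 2 (largest adjusted p = 0.00120). Those 14 leave out the mitochondrial covariate, no filter on low counts, limma-voom, the test against 1.5-fold, and the GC and length correction with the block. Whether JAG1 kept its call under these is not given here. The clone 1 count of 933 became 1512 with no filter on low counts, 115 in the test against 1.5-fold, 2322 with the replicate block, 2166 with the GC and length correction and the block, and 200 to 1301 with 1 library left out. The clone 2 count of 1008 became 1663 with no filter, 1653 in DESeq2, 123 against 1.5-fold, 2699 with the block, 416 in a fit of the 6 libraries compared, 2857 with the correction and the block, 80 with the mitochondrial covariate, and 237 to 1584 with 1 library left out. The shared count of 103 became 176, 26, 247 and 254 with no filter, against 1.5-fold, with the block and with the correction and the block, 27 with the covariate, and 45 to 127 with 1 library left out. The clone difference of 5733 became 983 against 1.5-fold, 391 with the covariate, and 3639 to 5782 with 1 library left out. The test against 1.5-fold asks for larger changes, and for all other changes, rises and falls with a library left out included, the cause was not tested. Within 1.5 times of the reported counts were 10, 7, 8 and 15 of 19 settings for clone 1, clone 2, shared genes and the clone difference. The median of all genes in the clone difference shifted to −0.137 with no filter and −0.142 in DESeq2, with 58.5% of calls higher before and 52.8% in DESeq2.

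Calls of named genes and clones gave 165 results and 2145 values under alternatives, of which 1809 stayed on their side of the threshold, 336 kept their direction but lost the call (323 with 1 library left out, 8 with the GC and length correction, 3 with RLE size factors, 2 in DESeq2), and 0 changed direction. The alternatives for named genes were these and the replicate block. They leave out the mitochondrial covariate, limma-voom and the test against 1.5-fold, among others. The 50 list results gave 200 values, of which 153 stayed, 40 lost the call (21 with an estimated correlation, 14 in fry, 5 with the correction) and 7 gained it. Of those 7, the replicate block gave 3, MHC class II genes in clone 1 (adjusted p = 0.0465) and cholesterol and TGF-beta and YAP lists in clone 2, the GC and length correction gave mitotic genes in clone 2, and fry gave Notch receptors, ligands and processing genes in clone 1 and growth factors and blood and endothelial markers in clone 2. Same-numbered libraries of wild type and clone 1 correlated at 0.245, 0.082 and −0.097, and those of the clones at 0.219, −0.021 and 0.012. Number 1 was the best match in these pairs of groups as well, while numbers 2 and 3 were not. All 3 numbers were best matches for wild type with clone 2 alone, so a block by number may join unlike libraries of clone 1. Segments of shifted expression numbered 1 and 5 with windows of 100 genes, against 5 and 11 with windows of 50, and the segment at the end of X in clone 1 was among those lost. Depth and 3 libraries per group limit small changes: of simulated 1.5-fold changes 30.3% were recovered in clone 1 and 10.4% in clone 2. Both clones were simulated with the same mean and dispersion per gene, so this gap cannot be read as a difference between the real clones.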

Other observations

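The lists and their tests were fixed with the others, while the genes named here were picked, and tested with each library left out, only after their values were seen. Of 33 hypoxia and glycolysis genes, 12 were higher and 5 lower in clone 2 than in clone 1, or 13 and 5 adjusted over the list alone. Among the higher members were HK1, a hexokinase, at 1.35 on the log2 scale (SE 0.18, adjusted p = 0.000111), HK2 at 1.19, GPI at 1.11, ENO1 at 0.97, ALDOA at 0.78 and PKM at 0.75. CA9, a carbonic anhydrase induced by hypoxia (−2.19, SE 0.33, adjusted p = 0.000326), ANKRD37 (−1.52), VEGFA (−1.16) and BNIP3 (−1.07) were lower. The list missed the threshold (camera adjusted p = 0.294), and no narrower list of its members was tested. Of 27 genes of the unfolded protein and amino acid responses, 4 were higher, among them SHMT2 (1.03), PHGDH (1.01) and PSAT1 (0.69), and 1 was lower (camera adjusted p = 0.195). Of 20 mesenchymal and EMT genes 8 were higher and 1 lower in clone 2 than in clone 1, with the same counts over the list alone: VIM (1.22), the transcription factors PRRX1 (1.45) and FOXC1 (0.86), and S100A4 (−2.31). Of 20 epithelial genes 8 were higher and 2 lower, again over the list alone, with KRT18 (1.26), KRT8 (1.16) and DSP, the desmosomal protein desmoplakin (1.17), higher and EPCAM (−0.98) and CLDN4, a tight junction protein (−0.81), lower. Both lists missed the threshold (camera adjusted p = 0.0954 and 0.214). The mesenchymal list passed with the replicate block (0.0323), after the GC and length correction (0.0378) and in fry (0.0196), but not with an estimated correlation (adjusted p = 0.667). Mitotic genes were higher for 10 of 30 members and lower for 2, with KIF11 (0.83), KIF20A (0.79) and PLK1 (0.75) higher (camera adjusted p = 0.0954, 0.0269 after the GC and length correction, 0.0370 in fry, and 0.672 with an estimated correlation).

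Of 42 interferon-stimulated genes 9 were lower in clone 2 than in clone 1, among them OASL (−3.52), IFIT1 (−1.76), IFIT3 (−1.58) and IFI27 (−1.41), and 5 were higher, among them IFITM3 (0.74), for a list median of −0.53 (camera adjusted p = 0.155, but 0.0175 with the replicate block). In the MHC class II list 4 of 10 were lower and CD74 was higher (1.18, camera adjusted p = 0.216). Of 14 homing and lymphangiogenesis genes PDPN was higher (0.69) and 4 were lower, with VEGFA and PDGFC (−0.59) among them and VEGFC at −0.51, a call lost without clone 1 replicate 1 (adjusted p = 0.0510; the list's camera adjusted p = 0.155, fry 0.0196). The growth factor genes EREG (−1.65) and AREG (−1.60) were lower, as 2 of 4 lower members of 26 (camera adjusted p = 0.397). Apart from VEGFC, the genes named in these paragraphs kept their difference between the clones with any 1 of the 9 libraries left out.

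The remaining lists missed camera's threshold between the clones. Camera adjusted p was 0.216 for Notch receptors, ligands and processing genes, 0.771 for matrix, 0.832 for inflammatory, 0.679 for MHC class I (median 0.08, direction down), 0.529 for stem cell, 0.679 for p53, 0.656 for cholesterol and 0.216 for ribosomal protein genes. It was 0.774 for luminal, 0.505 for basal, 0.505 for blood and endothelial markers, and 0.505 for histones. Of these, Notch receptors, ligands and processing genes (0.00466), stem cell (0.0370), basal (0.0230) and blood and endothelial markers (0.0196) passed fry. With an estimated correlation, the smallest camera adjusted p of all 25 lists between the clones was 0.667.

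Library composition differed between groups in other measures than the mitochondrial share. Replication-dependent histones took 0.0137 to 0.0149% of counts in the wild-type libraries, 0.0084 to 0.0108% in clone 1 and 0.0075 to 0.0078% in clone 2. Ribosomal protein genes took 6.34 ± 0.537% in wild type, 7.39 ± 0.433% in clone 1 and 6.01 ± 1.49% in clone 2 (SD, n = 3 each). Clone 2 replicate 1 had counts for 19905 genes, against 21395 to 24349 in the other 8 libraries, and a TMM factor of 0.861, and without it the clone 2 count was 1380.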
